A study of Homo sapiens with 3 samples.

How the data were processed

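RNA was measured by poly(A)-selected RNA sequencing in 3 libraries of RPE-1 cells, a human retinal pigment epithelial line immortalised with telomerase. The labels describe a derivative that carries GFP-tagged centrin 2 as a centriole marker and a PLK4 gene under a doxycycline-responsive promoter. All 3 libraries came from cells given a non-targeting control siRNA without PLK4 induction, so they form 1 group. Nothing in the labels says that the libraries came from separate cultures. The tests between libraries therefore measure only the spread between these 3 samples, which may be technical.

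The deposited values are whole-number counts of reads per gene for 58735 genes, not normalised. The submitters' processing notes name cutadapt 1.16, STAR 2.5.2a, featureCounts 1.6.2 and the hg38 build, without roles or settings. The annotation, the strand setting and the treatment of reads with several alignments or several overlapping genes are not given in the sources used here. All 58735 gene identifiers matched GENCODE release 29, and 99.513% of symbols were equal, so positions and exon lengths were taken from that release on hg38. The table also held 6 columns of per-sample counts that matched no sample label given here, and these were not used.

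Library totals were 49279692, 60040029 and 46625774 counts. TMM factors from edgeR 4.0.16 in R 4.3.3 were 0.985, 1.01 and 1.00 for libraries 1, 2 and 3, and CPM refers to the totals scaled by these factors. RPKM is CPM divided by the union of a gene's annotated exons in kb, which lowers the value of genes with long, rarely used exons. A gene counted as detected with a CPM of at least 1 in each of the 3 libraries. A count of 0 allows up to 3 counts, or 0.0618, 0.0494 and 0.0641 CPM in libraries 1, 2 and 3. Such floors and the exact binomial intervals at 95% confidence cover counting error only, since reads are not independent molecules. The chi-square test of each gene likewise sets the spread against counting error alone, so its calls may reflect technical spread.

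Because only 1 group was present, no test between groups was made. The spread of each gene was tested with a chi-square test of its 3 counts against the scaled library sizes (2 degrees of freedom) over 16293 genes with a mean count of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. A common dispersion was fitted with edgeR with an intercept only, after its expression filter. Pairs of libraries were compared by the chi-square statistic over the same genes. The 24 gene lists were fixed before the data were examined, together with 21 gene pairs, the tests, and the rule for the genes named. They gave 627 list memberships, and 4 symbols had no separate match. The counts of lists include 1 list that is not reported or drawn here. The level of a list is the median log2(RPKM + 0.1) of its detected members, placed among 10000 random lists of the same size drawn from detected protein-coding genes. The mean levels of 4 centrosome lists were compared by a two-sided permutation test over genes with 100000 resamples, adjusted over 6 pairs. The movement of a list is the range over the 3 libraries of its members' mean deviation in log2(CPM + 0.5). It was tested one-sided against 10000 random lists matched on mean count in 10 bins, for the 23 lists with at least 5 tested genes. Gene pairs were compared within each library as length-normalised ratios with a pseudocount of 0.5 count and a two-sided exact sign-flip test, whose smallest p with 3 libraries is 0.25. Genes are not independent replicates, so the tests across genes describe these libraries.

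The rule for named genes took PLK4, UNK, UNKL, CETN2, the members of the fixed pairs and the 10 most abundant genes. From each list it took the 2 highest and the lowest detected members, the most variable called member and members below detection. It also took the 15 called genes with the widest ratio of highest to lowest CPM among those with a mean count of at least 50. Genes without counts in a library have no such ratio and could not be chosen by their spread. JUNB, ATF3, NEAT1, EIF3C, NUSAP1, MZT2A, GAP43, DDIT4, XBP1 and DNAJB1 fell outside this rule and were chosen after their values were seen. The share of exon length that a gene has in common with other genes on the same strand was also computed after the values were seen. The limits of the 97.5 and 2.5 percentiles for calling a list high or low, and the tolerances used when comparing settings, were set after the data had been read.

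On simulated counts with the real means and library sizes, where 100 genes were raised 1.25-fold and 100 genes 2-fold in 1 library, the chi-square test recovered 59% and 78% of them among 16293 genes. It called 0.056% of the unchanged genes, and 6.16% of its calls were false. These counts held counting noise alone, so the rates do not cover the wider spread of the real libraries. Lists of 30 genes were drawn at random after each gene's deviations had been shuffled among the libraries. With no shift, 7% of 400 lists had an unadjusted p under 0.05, slightly above the nominal rate. With a shift of 0.2 on the log2 scale, 96.25% of 400 lists passed. Random lists set against random lists pass at about the nominal rate by construction. The shuffling also removed changes that genes share between the real libraries, so these rates may not hold for the real lists. Alternatives covered DESeq2 1.42.0 size factors and dispersions, library totals, other count and CPM limits, an added coefficient of variation, levels without length, other pseudocounts, all measured list members and leaving out each replicate in turn. A correction for GC content in 20 bins was added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.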

Results

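The deposited counts described RPE-1 cells carrying an inducible PLK4 gene and GFP-tagged centrin 2, sampled after control siRNA and without induction. The study concerns Unkempt, an RNA-binding protein, in centriole overduplication driven by PLK4. The 3 libraries analysed here are a control state, so the questions that could be addressed were which centrosome, translation and cell-state genes these cells expressed, and how far the libraries of this state differed. The libraries held 49279692, 60040029 and 46625774 counts.

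PLK4, the kinase that starts centriole duplication, was expressed at nearly the same level in the 3 libraries, with 63.95, 64.43 and 64.15 CPM (mean 64.2 ± 0.240 SD, 14.3 RPKM, n = 3). PLK4 (ENSG00000142731) lies on chromosome 4 from 127880861 to 127899195. Its spread did not exceed counting noise (chi-square test, adjusted p = 0.959). UNK (ENSG00000132478, chromosome 17, 75784771 to 75825799), which encodes Unkempt, stood at 63.6 ± 2.88 CPM or 11.4 RPKM (n = 3). Its paralogue UNKL (ENSG00000059145, chromosome 16, 1363205 to 1414751) stood at 30.01 ± 4.38 CPM or 4.005 RPKM (n = 3). Per unit of exon length, UNK exceeded UNKL 2.87-fold (log2 ratio 1.52 ± 0.27 SD, higher in 3 of 3 libraries, exact sign-flip p = 0.25, the smallest possible). CETN2 (ENSG00000147400, chromosome X, 152826973 to 152830777), the gene of the centriole protein centrin 2, reached 775, 647 and 683 CPM (364 RPKM). Unlike PLK4, UNK (adjusted p = 0.00367), UNKL (4.13e-14) and CETN2 (9.62e-141) had a spread beyond counting noise by the chi-square test. CETN2 stood 66.5-fold above CETN3 (log2 ratio 6.06, or 5.37 without length) and, with a floor of 3 counts per library for CETN1, at least 9714-fold above CETN1. Counts at PLK4 and CETN2 do not separate reads of the endogenous genes from reads of the inducible and the GFP-tagged copies.

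A CPM of at least 1 in every library was reached by 12615 genes. Of these, 11508 were protein-coding, 57.7% of the 19951 protein-coding genes in the table, and 265 were long intergenic noncoding RNAs. The most abundant transcripts were those of the mitochondrial genes MT-CO1 (12326 ± 3097 CPM, SD, n = 3), MT-ND4 (11350 ± 4615), MT-CO3 (7155 ± 1417) and MT-ATP6 (6106 ± 1993). With them stood the actin genes ACTB (11373 ± 1488) and ACTG1 (7148 ± 1226), the matrix gene FN1 (9876 ± 223), the intermediate filament gene VIM (7832 ± 331), the actin crosslinker FLNA (6955 ± 870) and the glycolytic gene GAPDH (6056 ± 874). These 10 genes held 8.61 ± 0.578% of counts.

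Nearly all centrosome genes were detected, with list medians from 3.72 RPKM for satellites to 6.97 RPKM for pericentriolar material. Of the genes for centriole duplication and structure, 32 of 33 were detected, with a median of 3.89 RPKM. CETN2 and PLK4 were the highest, and FGFR1OP was the lowest detected member (0.875 ± 0.0587 RPKM). Reads of the inducible PLK4 and the GFP-tagged centrin 2 copies may add to these ranks and to the PLK4 ratios below. SPICE1 fell below detection with 1.28, 0.642 and 1.26 CPM, and 34.6% of its exon length is shared with another gene on the same strand. PLK4 exceeded its cartwheel partners, SASS6 by 3.57-fold and STIL by 2.44-fold, and its recruiting scaffold CEP152 by 6.31-fold, each in 3 of 3 libraries. Without length the log2 ratio was 0.58 instead of 1.29 for STIL and 1.79 instead of 2.66 for CEP152. CEP192, the other scaffold that recruits PLK4, stood 2.19-fold above CEP152. Among Polo-like kinases, PLK4 was 7.69-fold below PLK2, 2.21-fold below PLK3 and 1.08-fold below PLK1.

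Of the pericentriolar material genes 30 of 32 were detected, with a median of 6.97 RPKM. TUBG1, the main gamma-tubulin gene, led at 56.4 ± 3.20 RPKM and stood 8.93-fold above TUBG2. MZT2B followed at 42.8 ± 7.97 RPKM, although MZT2A is a near-identical copy and reads may be divided between them. CNTLN was the lowest detected (1.21 ± 0.0530 RPKM), while NINL and HAUS7 (35.6% of exon length shared) had no counts in library 1. PCNT exceeded CDK5RAP2 by 1.19-fold. Of the centriolar satellite genes 28 of 29 were detected, with a median of 3.72 RPKM, led by MED4 (14.02 ± 1.47) and GABARAP (13.2 ± 2.23), with KIAA1328 lowest (0.363 ± 0.0609). GABARAP shares 30.5% of its exon length with another gene on the same strand. The satellite scaffold PCM1 exceeded CEP131 by 1.69-fold (log2 ratio 0.76, or 2.63 without length). Of the appendage genes 20 of 21 were detected, with a median of 5.15 RPKM, from NCS1 (31.0 ± 1.15) and the dynactin gene DCTN1 (20.9 ± 0.851) down to FBF1 (0.841 ± 0.206, 49.6% of exon length shared).

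Among the 6 comparisons of these lists, mean log2 levels differed only between pericentriolar material (2.85, 30 genes) and satellites (1.87, 28 genes), by 0.98 (permutation test over genes, adjusted p = 0.0234). Pericentriolar material minus duplication genes gave the next largest difference (0.79, adjusted p = 0.102, permutation test). With members below detection included, the difference from satellites was 0.81 and no longer passed (adjusted p = 0.436, permutation test). Within detected protein-coding genes, the medians lay at the 5.07 percentile of random lists for duplication genes, 66.8 for pericentriolar material, 4.53 for satellites and 31.0 for appendages. Against all protein-coding genes, with every member included, they lay at 92.89, 99.65, 91.49 and 94.38. Without length they lay at 17.75, 83.47, 12.56 and 64.24 within detected genes.

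**Figure D1:**
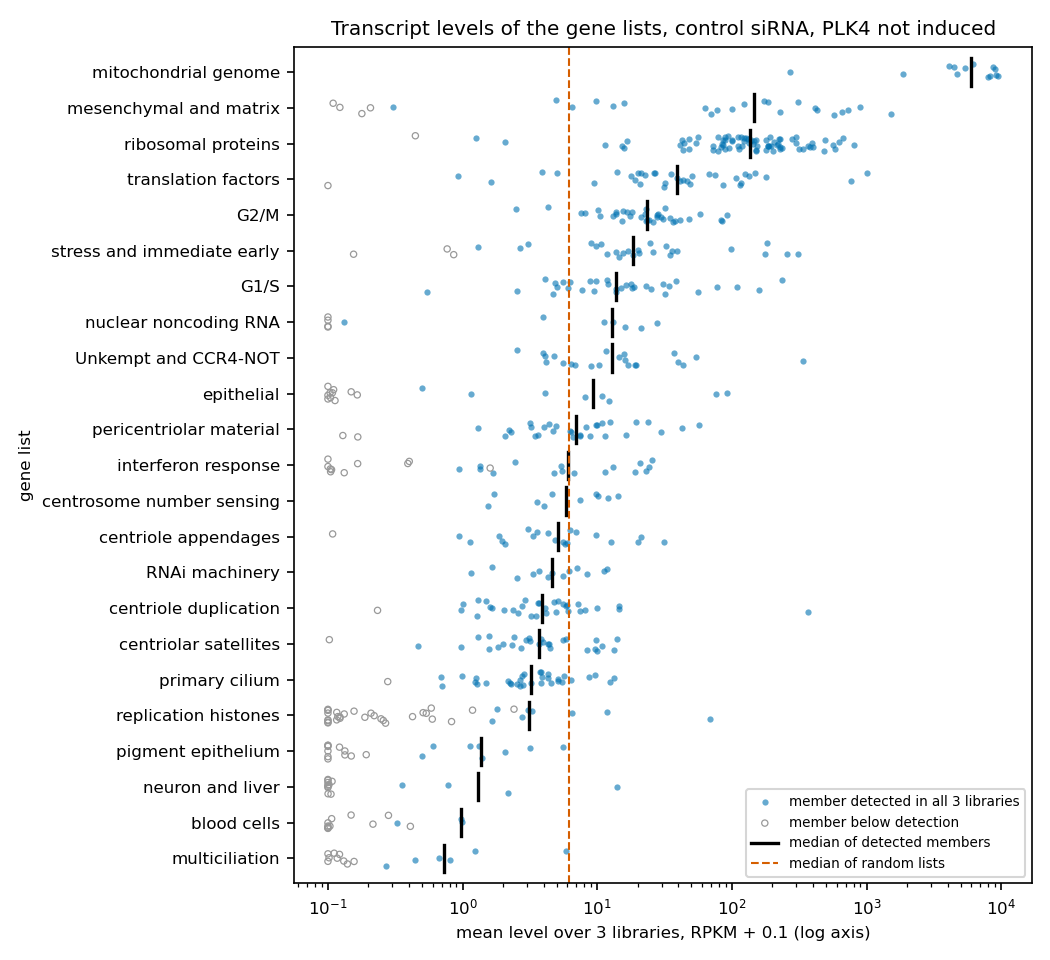
Mean level of every member of 23 gene lists over the 3 libraries, in RPKM + 0.1 on a log axis, one row per list. Filled points are detected members, open points are members below detection, black bars are the medians of detected members and the dashed line is the median of random lists of detected protein-coding genes. Mitochondrial, matrix and ribosomal protein genes lie highest (medians of 5917, 145 and 135 RPKM), and centriole duplication and satellite genes lie near 3.89 and 3.72 RPKM.

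Genes for the primary cilium were expressed, and those for motile multicilia mostly were not. Of the intraflagellar transport, BBSome and transition zone genes, 33 of 34 were detected, with a median of 3.21 RPKM. KIF3B, a kinesin of anterograde transport, reached 13.3 ± 1.45 RPKM and IFT57 12.4 ± 0.171, while BBS5 stood at 0.596 ± 0.118 (n = 3). BBS1 was below detection, and 53.9% of its exon length is shared with another gene on the same strand. The list lay at the 1.32 percentile among detected genes and at 87.96 against all protein-coding genes, and at 5.04 among detected genes without length, outside the limit of 2.5. Of the 15 multiciliation genes 6 were detected (percentile 0.04, or 9.59 with all members against all protein-coding genes), with CCNO highest at 5.75 ± 1.20 RPKM, MCIDAS at 1.14 ± 0.101 and DNAH5 lowest at 0.168 ± 0.0217. FOXJ1, the master regulator of motile cilia, had 5, 2 and 0 counts, and DEUP1, a gene of the deuterosome, had none.

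All 22 genes of the list around Unkempt, the CCR4-NOT deadenylase and poly(A)-binding proteins were detected, with a median of 12.9 RPKM (98.6 percentile). PABPC1, the main cytoplasmic poly(A)-binding protein, stood at 336 ± 56.5 RPKM, 9.10-fold above PABPC4. BTG2, which binds the deadenylase, stood at 54.2 ± 7.09 RPKM and CNOT6L was lowest at 2.44 ± 0.357. Among the catalytic subunits CNOT6 exceeded CNOT6L 2.56-fold. CNOT8 exceeded CNOT7 1.79-fold per unit of length, but CNOT7 had more counts (log2 ratio 0.64 without length), so their order depended on the length used.

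Translation genes were among the most abundant. Of the translation factors 35 of 36 were detected, with a median of 39.2 RPKM, led by EEF1A1 (1003 ± 65.0) and EEF2 (763 ± 45.7), the elongation factors. Ribosomal protein genes had a median of 135 RPKM with 78 of 79 detected, led by RPS2 (805 ± 23.2) and RPS12 (668 ± 128). Some members had very few counts where other genes overlap them. EEF1G had 0 counts in each library, and 99.9% of its exon length is shared with a second annotated gene. EIF4A1 had 291, 227 and 155 counts with 48.6% shared, and stood 51.4-fold below its paralogue EIF4A2. RPS10 had 40, 70 and 22 counts with 39.4% shared, and RPL36A was the lowest detected ribosomal protein gene (1.15 ± 0.219 RPKM). Ribosomal protein, EIF4A1 and EIF3C reads can also fall on pseudogenes or near-identical copies, so these low values are uncertain.

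Proliferation genes were high. All 36 G2 and mitosis genes were detected (median 23.2 RPKM, 100 percentile), led by TOP2A (92.4 ± 9.75 RPKM), the mitotic topoisomerase, and ANLN (84.6 ± 3.35), with PRC1 lowest (2.39 ± 0.183). The exons of PRC1 and NUSAP1 are shared by 57.6% and 62.2% with other genes on the same strand. All 33 G1/S genes were detected (median 13.8 RPKM, 99.77 percentile), from PCNA (236 ± 12.5), the replication clamp, and CCND1 (158 ± 6.36) down to E2F2 (0.439 ± 0.142). CCNB1 exceeded CCNE1 by 12.01-fold. CDKN1A, the cell cycle inhibitor p21, stood at 697 ± 53.9 RPKM, 18.0-fold above MDM2 (log2 ratio 4.17, or 2.04 without length).

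All 10 genes that sense abnormal centrosome number were detected (median 5.86 RPKM, 45.8 percentile, or 92.52 with all members against all protein-coding genes), among them TRIM37 (11.9 ± 0.356), with CRADD lowest (1.45 ± 0.212). PIDD1, of the PIDDosome, stood at 3.91 ± 0.909 RPKM. Of the interferon-stimulated genes 16 of 26 were detected (median 6.02 RPKM, 47.4 percentile, or 10.7 without length and 30.29 without library 1), led by TMEM173, which encodes STING (25.4 ± 1.59), and IFIT3 (24.3 ± 3.57), with OAS2 lowest detected (0.848 ± 0.143). IFNL1 and RSAD2 had 0 counts, and IFNB1 and CXCL10 had 1 count each over the 3 libraries. All 13 genes of the siRNA and miRNA machinery were detected (median 4.61 RPKM, 26.0 percentile, or 79.1 without length and 88.19 with all members against all protein-coding genes), from DROSHA (11.8 ± 1.51) and TARBP2 (11.1 ± 1.63) down to AGO3 (1.04 ± 0.0984).

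Matrix and mesenchymal genes were mostly detected, while most listed genes of pigment epithelium and of other epithelia were below detection. Of the matrix and mesenchymal genes 22 of 26 were detected, with a median of 145 RPKM (100 percentile), led by VIM (1518 ± 64.2) and LGALS1 (894 ± 244), with COL1A2 lowest detected (0.203 ± 0.0363). COL3A1, COL5A1, COL6A2 and POSTN were below detection. Of the epithelial genes 8 of 18 were detected (77.47 percentile, or 8.19 with all members against all protein-coding genes), with KRT8 (92.2 ± 13.2) and KRT18 (76.4 ± 12.6) highest and OCLN lowest (0.401 ± 0.0810). CDH1, which encodes E-cadherin, had 0, 5 and 5 counts. Of the 19 pigment epithelium genes 8 were detected (percentile 0.47, or 8.91 with all members against all protein-coding genes), led by the transcription factors OTX2 (5.47 ± 0.239) and MITF (3.05 ± 0.253), with SERPINF1 lowest (0.402 ± 0.105). RPE65, the visual cycle isomerase, had 8, 6 and 0 counts, and TYR, DCT and TTR had none.

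Most markers of other cells were below detection, although the neuron marker SYT1 was not. Of 14 blood cell markers 3 were detected (percentile 2.84, or 6 with all members against all protein-coding genes), CORO1A at 0.889 ± 0.0447, LCP1 at 0.879 ± 0.106 and PTPRC at 0.225 ± 0.0841 RPKM, and HBB had 0 counts. Of 14 neuron and liver markers 4 were detected (percentile 2.28, or 0.36 without length and 0.69 with all members against all protein-coding genes), SYT1 at 13.9 ± 0.454 RPKM, SNAP25 at 2.09 ± 0.130, GAP43 at 0.678 ± 0.125 and SERPINA1 lowest at 0.252 ± 0.0548. ALB had 0, 2 and 1 counts. Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, were detected for 8 of 37 genes, from HIST1H2BK (68.5 ± 12.6 RPKM) and HIST1H1C (11.7 ± 3.36) down to HIST1H2AG (1.54 ± 0.329). The list lay at the 10.9 percentile, or at 0.04 without length, below the limit of 2.5, although near-identical histone copies can divide reads. Of 11 nuclear and structural noncoding RNAs 7 were detected (89.0 percentile), led by GAS5 (27.7 ± 1.84 RPKM) and MALAT1 (20.9 ± 9.07), with KCNQ1OT1 lowest (0.0323 ± 0.0110). RN7SL1, RN7SK, RMRP and RPPH1 had 0 counts, and 100% of the exon length of each is shared with another annotated gene.

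The libraries differed in many genes, and library 1 stood apart. Of the 15 most variable genes, EGR1, EGR2, EGR3 and FOSB, which encode transcription factors, belong to the list of stress and immediate early genes and were highest in library 1. EGR3 stood at 9.07 CPM in library 1 against 1.37 and 0.620 in libraries 2 and 3, and FOSB at 124 against 22.8 and 14.98. EGR1 stood at 133 CPM against 33.1 and 25.4, EGR2 at 5.15 against 1.30 and 0.940, and the chemokine genes CXCL3 at 3.01 against 0.708 and 0.342 and CXCL2 at 2.41 against 0.494 and 0.684. HRK, RPS19P3, B3GALT1 and MIR1244-2 were also highest in library 1. JPH3 went the other way, with 0.144 CPM in library 1 against 1.32 and 1.73, and CPNE5, ACKR3, LRP5L and HIST1H2AI were lowest there too. Of these 15 genes only FOSB and EGR1 count as detected. The other ratios rest on at least 1 low value, such as 7 counts for JPH3 in library 1. RPS19P3, MIR1244-2, HIST1H2AI, CXCL2 and CXCL3 have near-identical copies, and their counts are uncertain.

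**Figure D2:**
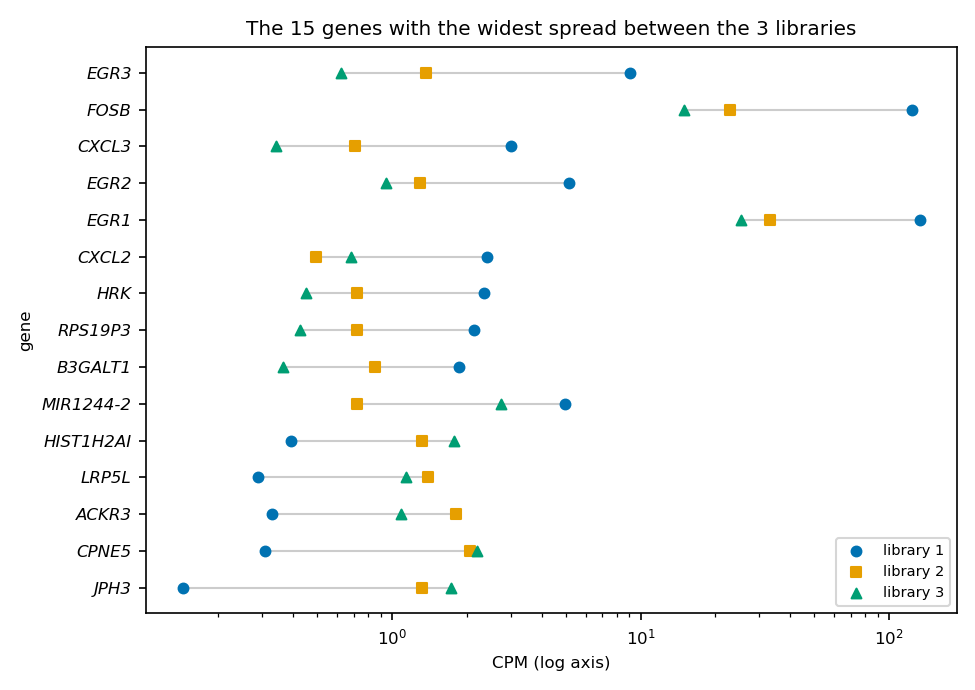
CPM of the 15 called genes with the widest ratio of highest to lowest library, on a log axis. Only genes with a mean count of at least 50 and counts in every library were eligible, and only FOSB and EGR1 of those shown count as detected. Circles, squares and triangles are libraries 1, 2 and 3, and grey lines join the lowest and highest. Library 1 is the highest or the lowest point in each row, for example at 124 CPM for FOSB and 0.144 CPM for JPH3.

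Over all genes, the spread exceeded counting noise in 11182 of 16293 tested genes (68.6%), with a median ratio of highest to lowest CPM of 1.27. With an extra coefficient of variation of 0.05 allowed for each gene, 5322 genes were called. Of the 11182 genes called without that allowance, library 1 was the farthest from the other two in 7427 (66.4%), library 2 in 2175 and library 3 in 1580. Among called genes with counts in every library, 1515 reached a ratio of at least 2. Of these, 833 were highest and 574 lowest in library 1. Called genes without counts in a library have no such ratio. They are missing from these numbers and from the median ratio, so genes absent from library 1 are not among the 574. The common biological coefficient of variation from edgeR was 0.135. Without library 1 it was 0.0603, and 4581 genes were called, of which 4528 were among the 11182. The SD of log2 ratios between libraries was 0.355 for 1 and 2, 0.351 for 1 and 3 and 0.187 for 2 and 3. The chi-square statistic per degree of freedom was 98.1, 64.2 and 10.005 for the same pairs, so no 2 libraries agreed within sampling noise, which does not show that they came from separate cultures. Library 1 had counts in 19953 genes, fewer than the 23050 in library 3, although library 3 had a lower total, and library 2 had counts in 24416. There were 2785 genes with counts in libraries 2 and 3 and none in library 1, against 261 absent only from library 2 and 560 absent only from library 3. Whether the distance of library 1 arose in the cells or in the preparation of the library was not tested.

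Of the 23 lists tested, 6 moved between libraries by more than genes of like abundance. Transcripts of the mitochondrial genome were higher in library 1 for all 13 genes, and all 13 passed the chi-square test. Their mean deviations were 0.54, -0.36 and -0.18 in libraries 1, 2 and 3 (log2, range 0.90, adjusted p = 0.000575 against random lists). Without library 1 the range was 0.18 and still passed (adjusted p = 0.000575). MT-ND4 stood at 16649 CPM in library 1 against 8215 and 9186, and MT-ATP8 at 3020 against 1324 and 1572. Mitochondrial protein-coding genes took 9.07%, 5.19% and 5.71% of counts. The same adjusted p, which rests on the smallest p of 1e-04 that the random lists can give, was reached by stress genes, G2/M genes and ribosomal protein genes.

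Of the stress and immediate early genes 25 of 28 were detected (median 18.3 RPKM, 99.98 percentile, or 95.27 without length, no longer past the limit for a high list), led by the chaperone genes HSP90B1 (311 ± 7.44) and HSPA8 (255 ± 13.4), with CHAC1 lowest (1.20 ± 0.106). They had mean deviations of 0.33, -0.08 and -0.25 (range 0.58), with 26 of 28 variable over all genes tested and 26 adjusted over the list alone. Of the variable members 16 were highest and 9 lowest in library 1, and the median deviation there was 0.13, below the mean. Besides EGR1, EGR2, EGR3 and FOSB, JUNB stood at 1.94 times and ATF3 at 1.90 times the mean of the other two libraries in library 1. HSPA8 (1.07 times) and HSP90B1 (0.964 times) stayed close to it. Without library 1, the range was 0.18 and still passed (adjusted p = 0.000575).

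G2/M genes were lower in library 1 and higher in library 3, with mean deviations of -0.13, 0.01 and 0.11 (range 0.24), and 28 of the 34 variable members were lowest in library 1. The range was 0.099 without library 1 (adjusted p = 0.000575) and 0.159 without library 3 (adjusted p = 0.0109). CDC20, the activator of the anaphase-promoting complex, stood at 60.4, 83.7 and 87.8 CPM. G1/S genes went the same way by less (-0.08, -0.01 and 0.09, range 0.17, adjusted p = 0.00874), with E2F2 at 1.52, 2.996 and 2.67 CPM. The G1/S range was 0.106 without library 1 (adjusted p = 0.000575) and no longer passed without library 3 (0.078, adjusted p = 0.394). PLK1 stood at 68.7, 77.0 and 76.3 CPM, while PLK4 did not vary.

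Ribosomal protein genes were lower in library 1, with mean deviations of -0.14, 0.06 and 0.08 (range 0.22), and 61 of 78 variable members were lowest there. RPL39 stood at 57.3 CPM in library 1 against 104.2 and 104.1. Without library 1 the range was 0.018 and did not pass (adjusted p = 0.455). Nuclear and structural noncoding RNAs had mean deviations of 0.21, -0.16 and -0.05 (range 0.37, adjusted p = 0.0107), and the median of library 3 was 0.02, opposite in sign to its mean. MALAT1 stood at 277 CPM in library 1 against 142 and 135, while GAS5 stood at 93.0 against 104.7 and 104.5. Of the 6 variable members 2 were highest and 2 lowest in library 1, and RN7SL2, the most variable, was highest in library 3 (5.77, 2.32 and 6.26 CPM). This range did not pass without library 1 (0.119, adjusted p = 0.120) or without library 2 (0.255, adjusted p = 0.0933).

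The other 17 lists did not pass. Their ranges were 0.062 for centriole duplication, 0.122 for pericentriolar material, 0.070 for satellites, 0.043 for appendages and 0.055 for the primary cilium, with adjusted p between 0.0930 and 0.730. Unkempt and CCR4-NOT genes had a range of 0.093 (adjusted p = 0.298), translation factors 0.109 (0.0906) and interferon-stimulated genes 0.172 (0.106). Without library 1, satellites passed (0.071, adjusted p = 0.0414). Spread beyond counting noise was called in 27 of 33 duplication, 26 of 31 pericentriolar material and 18 of 28 satellite genes. It was also called in 14 of 20 appendage, 21 of 34 primary cilium and 21 of 22 Unkempt and CCR4-NOT genes. The share over all tested genes was 68.6%. Among the called members were UNKL (24.99, 33.09 and 31.96 CPM, adjusted p = 4.13e-14 by the chi-square test) and NPHP4 (10.7, 18.8 and 16.7 CPM).

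**Figure D3:**
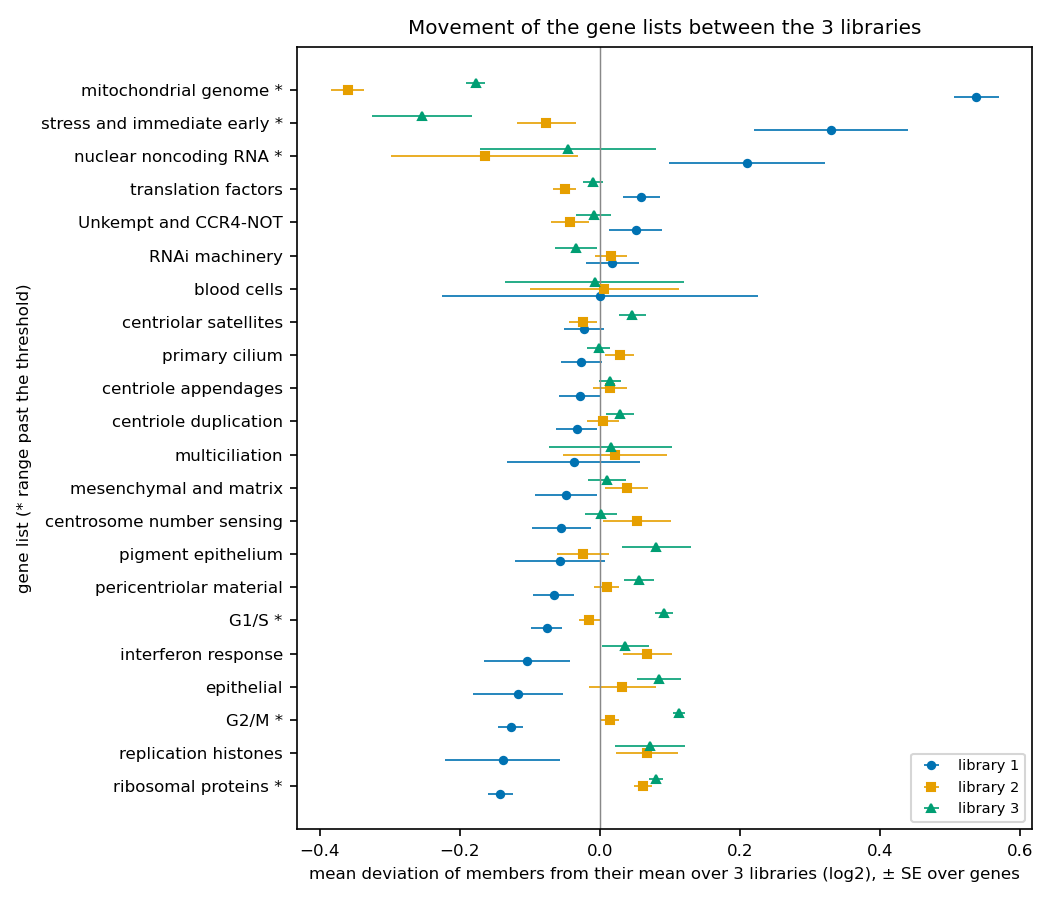
Mean deviation of each list's tested members from their own mean over the 3 libraries, in log2 units, with the standard error over genes, for 22 lists. Circles, squares and triangles are libraries 1, 2 and 3, and an asterisk marks the 6 lists whose range passed the threshold. Library 1 lies at 0.54 for the mitochondrial genome and -0.14 for ribosomal proteins, and pericentriolar material lies at -0.07, 0.01 and 0.06 in libraries 1, 2 and 3.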

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

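The count of detected genes, of lists at the extremes, of lists that moved and of pairs ordered alike in the libraries stayed within 1.5 times its main value in every alternative run. The number of variable genes was 5322 with an extra coefficient of variation of 0.05 and ranged from 4581 (without replicate 1) to 10016 (without replicate 3) when replicates were left out, where the cause was not tested. The biological coefficient of variation ranged from 0.0603 without replicate 1 to 0.170 without replicate 3. No centrosome list difference passed with all measured members (0 against 1), where the lists by construction also held members below detection. With all measured members the primary cilium list moved from the 1.32 to the 87.96 percentile, where the background by construction also held undetected genes. Without length 13 of the 24 list percentiles moved beyond the spread between libraries. CNOT7 over CNOT8 turned to 0.639 (log2) without length, by construction, and of the other 20 pairs, which kept their direction, 14 moved by more than their SD. The 6 lists that moved also passed with DESeq2 size factors, library totals, a mean count of at least 50 and the GC trend removed, the last chosen after seeing the data. Without replicate 1 there were also 6, but ribosomal and noncoding RNA lists were replaced by satellites and 1 list not reported here. With 3 libraries no test of a pair can pass the threshold, and depth limits genes near the floor of 0.0494 to 0.0641 CPM. No paired analysis was possible because only 1 group was analysed.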

Other observations

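The stress list also held genes that did not follow EGR1 and FOSB. DDIT4, a stress-induced inhibitor of growth signalling, stood at 0.648 times the mean of the other two libraries in library 1, and XBP1 and DNAJB1, of the unfolded protein and heat shock responses, at 0.818 and 0.828 times. The abundant genes ACTB and ACTG1 stood at 0.799 and 0.736 times. Variable matrix and mesenchymal genes went both ways, with 10 highest and 12 lowest in library 1 (adjusted p = 0.350 for the list range), among them LGALS1 at 0.602 and VIM at 1.07 times. The sequencing libraries also differed in how ratios followed GC content across genes, which are not independent replicates. Spearman's rho of the log2 ratio with GC content was -0.304 for libraries 1 and 2, -0.123 for 1 and 3 and 0.394 for 2 and 3.

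The tests below were written before their values were seen, but after the patterns had been found in the same data, so each explanation is a hypothesis, and no biological explanation was tested because the design holds 1 group. The list of stress and immediate early genes was higher in library 1 on average, with 16 variable members highest and 9 lowest there. A GC trend between libraries is an unlikely cause, since 1.07 times the range was left after its removal. Induced cells in library 1 would raise PLK4, but PLK4 stood at 0.995 times the mean of the other two. For more nuclear RNA in library 1 the prediction was met, since MALAT1 and NEAT1 were higher there by 0.81 (log2) against 0.50 ± 0.17 (SE) for the list. However, EGR3 (9.13 times) and FOSB (6.57 times) exceeded MALAT1 (2.002 times). Of the 6 variable nuclear and structural noncoding RNAs, 2 were highest and 2 lowest in library 1. That list is not limited to nuclear-retained RNAs, so this split cannot decide the question either way. All 13 transcripts of the mitochondrial genome, which are not nuclear, were also highest in library 1, which more nuclear RNA alone would not give. MALAT1 and NEAT1 therefore do not decide the question, and handling before lysis stays open as untested.

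Mitochondrial transcripts were higher in library 1. A GC trend could not be the whole cause, since 0.959 of the range remained after its removal (0.86, adjusted p = 0.000575). Mitochondrial DNA carried into the library would add about the same RPKM to each gene. The highest excess, 7594 RPKM for MT-ATP8, was 44.2 times the lowest, 172 RPKM for MT-ND6. MT-ATP8 is only 0.207 kb long and shares 22.2% of its exon length with MT-ATP6. The values argue against DNA as the only cause but do not exclude a smaller contribution. A difference in cell state or in RNA selection may remain, and was not tested.

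G2/M genes were lower in library 1 and higher in library 3. A GC trend is an unlikely cause, since 0.997 of the range remained after its removal (0.24, adjusted p = 0.000575). A difference in the share of dividing cells, for example from plating density, stays open as untested, and the labels give no batch or day.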
